A study of Mus musculus with 4 samples.

How the data were processed

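RNA was measured by sequencing in regulatory T (Treg) cells, the CD4+ T cells that express Foxp3 and restrain immune responses. The cells were sorted from spleens of male mice aged 16 weeks that carried a Foxp3-driven Cre. The groups were 2 wild-type (WT) libraries and 2 libraries from mice with floxed Tcf7 and Lef1 (the genes of the proteins Tcf1 and Lef1), called dKO here. Samples were assigned to groups by their titles. Total RNA was extracted on columns and libraries followed an Illumina protocol, per the labels' protocols.

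The authors used FastQC, TopHat2 2.1.0, Cuffdiff 2.2.1 and the mm10 mouse genome, per the submitters' processing notes. The gene annotation, read length, strand setting and any read filter are not given in the sources used here. The authors deposited a table of 24346 gene rows with FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) for each of the 4 libraries and as a mean per group. The deposited table also held the authors' log2 fold changes and their p-values and q-values. Shorter lists deposited by the authors held 185 genes higher and 147 genes lower in dKO. Tested against the full table, these were exactly the 332 genes with a q under 0.05, a fold of at least 1.5 and an FPKM of at least 1 in the higher group. The smallest q in the authors' deposited table was 0.00365, shared by 179 genes.

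The library columns carried the suffixes 0 and 1, while the sample titles number replicates from 1. Each column was therefore tied to its group and not to a titled replicate, and the libraries are called WT_0, WT_1, dKO_0 and dKO_1. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

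FPKM are not counts, so no count test was run. The values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, unpaired, Benjamini-Hochberg adjustment). Rows with an FPKM of at least 1 in at least 2 of the 4 libraries entered the test, which left 11595 rows. A row is called when its adjusted p was under 0.05. Differences are dKO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. The fit had 2 residual degrees of freedom and 2.31 prior degrees of freedom. On values simulated for this comparison over the same rows, the test called 65% of 100 genes changed by 1 on the log2 scale and 97% of 100 changed by 3. It made 173 calls, of which 6.36% were unchanged genes, and called 0 genes and 0 lists where no change was simulated. The simulated values were drawn independently for each gene.

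Gene lists and the rule for named genes were fixed before the data were examined. The 23 biology lists were Treg identity, Treg suppressive molecules, effector Treg, resting and naive T cell, follicular helper and follicular regulatory, Th1, Th2, Th17, cytotoxic and CD8 lineage, inhibitory receptors, Wnt/beta-catenin targets, cell cycle, early activation, type I interferon response, chemokine receptors and homing, survival and apoptosis, IL-2 and STAT5 axis, TGF-beta axis, T cell transcription factors, glycolysis, oxidative phosphorylation, cholesterol synthesis and ribosomal proteins. Further lists covered heat shock, replication-dependent histones, mitochondrially encoded genes (0 of which were in the table) and sex-linked genes, and markers of B cells, plasma cells, monocytes and macrophages, neutrophils, dendritic cells, NK cells, CD8 T cells, conventional CD4 T cells, erythroid cells and platelets, and general T cells. Called members were counted over all rows tested and adjusted over the list alone. Each list was set against the other rows with camera at a preset correlation of 0.01, adjusted over the 23 biology lists, and again with a correlation estimated from the data. Of the 14 lists called at the preset correlation, 0 held with an estimated correlation. With an estimated correlation, camera also rests on the 2 residual degrees of freedom, so the bar is high whatever the correlation. For resting and naive T cell genes the estimate was 0.0103, near the preset 0.01, yet the unadjusted camera p went from 1.3e-06 to 0.0403. A call lost there is therefore not by itself due to correlation between genes. In the simulation, a cell cycle list shifted by 0.5 was recovered and 0 other lists were called beside it. The simulated genes were independent, while the estimated correlation was 0.867 for cell cycle and 0.877 for ribosomal protein genes. The simulation therefore cannot show how often lists of correlated genes are called falsely at the preset correlation.

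The genes named are Tcf7, Lef1, Foxp3, Il2ra, Ctla4 and Ikzf2, the 10 called rows with the largest difference in each direction whose higher group reached a mean FPKM of 1, and up to 4 called members per list. Small RNA rows took many of these places. After the values were seen, the rule was extended to all called rows that are not small RNAs and to up to 4 members per list from the authors' lists. Other genes that are named were chosen after their values were seen.

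Gene positions are from GENCODE mouse release 21 on GRCm38, the assembly of mm10. By symbol or synonym, 23976 rows were matched. The authors' annotation may differ, so the positions locate genes and do not show which exons were counted. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Among the genes named, such overlaps are annotated for Dzip1, Tmprss13, Gbp2 and Pim1, besides those given with their values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made tables and figures.

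Low FPKM step by what 1 read is worth. Over genes with 1 annotated transcript longer than 1000 nucleotides and an FPKM under 0.3, the most common step corresponded to 18900000 reads in WT_0, 22800000 in WT_1, 22800000 in dKO_0 and 24800000 in dKO_1. These depths are estimates, and no whole reads were recovered. An FPKM of 0 can be a failed estimate: 190 rows, 0 of them protein-coding, were listed at 0 in a library and above 20 in another.

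The alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter at an FPKM of 5, quantile normalization, median centring, limma without the trend and with robust moderation, the column suffix as a block, each library left out, and other thresholds. Leaving out the 1312 rows of small RNA genes before the test was added after the data were seen.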

Results

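The series compared the transcriptomes of splenic Treg cells from WT mice and from mice with floxed genes for Tcf1 and Lef1, related DNA-binding proteins that act in T cell development and Wnt signalling. The cells were Thy1.2+ CD4+ and carried the Foxp3-Cre-GFP reporter. There were 2 WT and 2 dKO libraries, at estimated depths of 18900000 to 24800000 reads. The number of genes with an FPKM of at least 1 was 11611 in WT_0, 11474 in WT_1, 11396 in dKO_0 and 11446 in dKO_1. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.932 between the WT libraries, 0.961 between the dKO libraries and 0.933 to 0.953 between libraries of different groups. WT_1 correlated more with dKO_0 (0.953) and dKO_1 (0.947) than with WT_0. Of 4 sex-linked genes tested, limma called 0, with 0 at an unadjusted p under 0.05.

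The targeted genes were lower in both dKO libraries than in both WT libraries, but neither passed the test over all genes. Tcf7 (mouse chromosome 11, 52252371 to 52283014, minus strand, GRCm38) had 327 ± 25.4 FPKM (SD, n = 2) in WT and 248 ± 1.92 (SD, n = 2) in dKO. The log2 difference was -0.39 (SE 0.0789, limma adjusted p = 0.158). Lef1 (chromosome 3, 131110471 to 131224356, plus strand) had 63.2 ± 4.68 FPKM (SD, n = 2) in WT and 38.7 ± 3.79 (SD, n = 2) in dKO. Its log2 difference was -0.70 (SE 0.0984, limma adjusted p = 0.113). Adjusted over the list alone, both fell. In WT_0, WT_1, dKO_0 and dKO_1, Tcf7 had 345, 309, 247 and 249.6 FPKM, and Lef1 had 59.9, 66.5, 41.3 and 36 FPKM. In the authors' deposited table, Tcf7 had a q of 0.153 and Lef1 a q of 0.00365, and only Lef1 was listed as lower. A gene-level FPKM sums all exons, including any outside the floxed part, so these values do not measure the deletion. An annotated gene on the opposite strand, Gm43352, overlaps Lef1. With small RNA rows left out, an alternative chosen after seeing the data, Lef1 had an adjusted p = 0.0353, within a range of 0.0317 to 0.521 over its alternatives.

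Over all genes, dKO Treg cells had more transcripts of Gzmb, Mmp9, Csf1 and Ccl1, among other called genes. Gzmb, the granule protease granzyme B (chromosome 14, 56258838 to 56262260, minus strand), rose from 8.67 ± 0.46 FPKM to 89.7 ± 7.99 (SD, n = 2 each; log2 difference 3.23, SE 0.0883, limma adjusted p = 0.00255). Mmp9, a secreted matrix metalloproteinase, rose from 2.46 ± 0.108 FPKM to 16.2 ± 1.96 (log2 difference 2.31, adjusted p = 0.0126). Csf1, a macrophage growth factor, rose from 16.2 ± 2.59 FPKM to 74.2 ± 2.08 (log2 difference 2.13, adjusted p = 0.0181), and the chemokine Ccl1 from 4.4 ± 0.173 FPKM to 19.7 ± 2.65 (log2 difference 1.93, adjusted p = 0.0206). Also higher were Podnl1 (1.26), Tmprss13 (1.27) and Snx9 (1.08, log2 differences). Among lower genes, Dzip1, which acts at primary cilia, fell from 13.2 ± 1.5 FPKM to 3.44 ± 0.126 (log2 difference -1.67, adjusted p = 0.0272). Ccdc109b (-1.26), Nsg2 (-0.97) and Ift80 (-0.94, log2 differences) were lower too. Klk1b22, a kallikrein-family gene, was listed at 0 in both WT libraries and at 12.2 and 10.4 FPKM in dKO_0 and dKO_1. These values lie under the FPKM of 20 used above to look for failed estimates. Whether its 0 in WT is a failed estimate was therefore not checked. Also called were Serpina3g (log2 difference 1.69), Lilr4b (1.35, overlapped by Gm49339 on the same strand), the ubiquitin gene Ubb (-0.92) and Gm14085 (-1.04).

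In all, limma called 40 of 11595 rows, 21 higher and 19 lower in dKO. Small RNA rows made up 15 of these and other genes 25, 16 higher and 9 lower. All 25 were in the authors' deposited lists in the same direction. Without WT_0 the test called 177 rows, without WT_1 217, without dKO_0 2 and without dKO_1 2. All 25 genes kept their sign without WT_0 and without WT_1. Without dKO_0 or without dKO_1 the calls of these genes were lost, while 24 kept their sign and Klk1b22 left the filter. Each such fit left 1 library in a group. Hardly any row was called without dKO_0 or dKO_1, so the loss is not particular to these genes. With small RNA rows left out, it called 186 genes, 128 higher and 58 lower, including the 25.

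**Figure D1:**
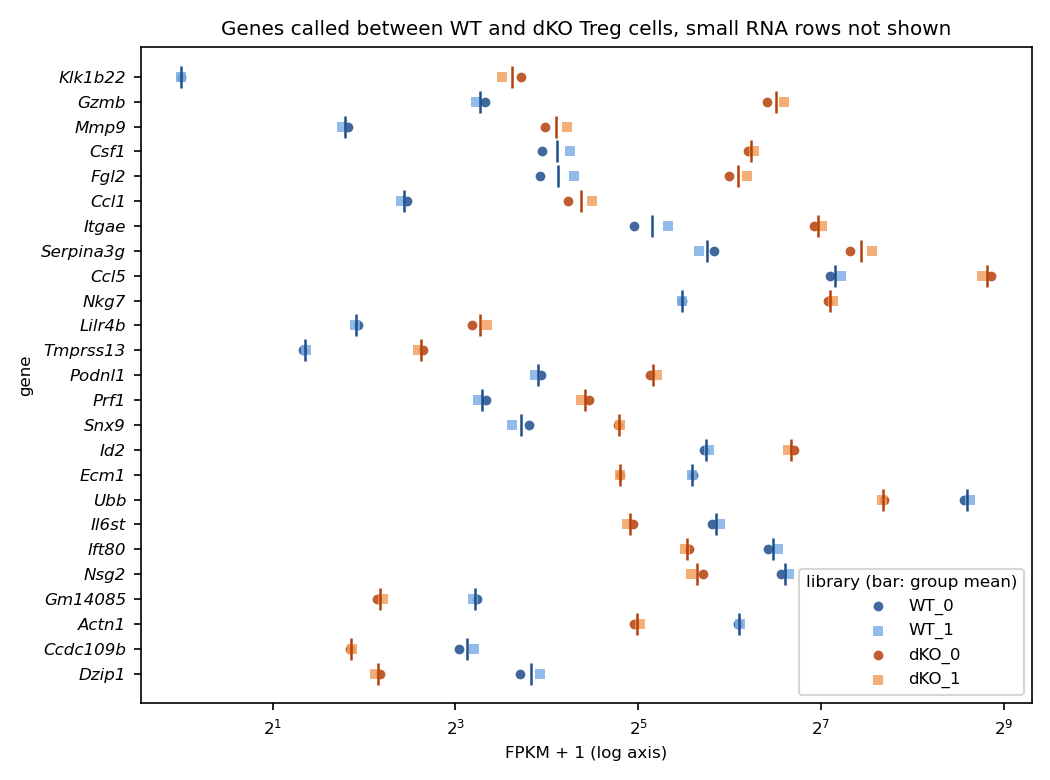
FPKM + 1 on a log axis for the 25 called genes that are not small RNAs, with circles for suffix 0, squares for suffix 1 and bars at group means. The plot shows 16 genes higher and 9 lower in dKO, with Gzmb at a mean of 8.67 FPKM in WT and 89.7 in dKO.

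Genes of cytotoxic lymphocytes and Th1 cells leaned higher in dKO. Of 22 tested members of the cytotoxic and CD8 lineage list, 5 rose, 0 fell and 17 did not pass. Adjusted over the list alone, 12 were higher and 3 lower. Besides Gzmb, the pore-forming protein gene Prf1 rose from 8.78 ± 0.412 FPKM to 20.4 ± 0.996 (adjusted p = 0.0286), the granule protein gene Nkg7 from 43.6 ± 0.0211 FPKM to 136 ± 3.74 (adjusted p = 0.00516) and the chemokine gene Ccl5 from 142 ± 8.41 FPKM to 449.5 ± 21.9 (SD, n = 2 each; limma adjusted p = 0.0126). Itgae, the CD103 integrin chain that binds E-cadherin, rose from 34.5 ± 6.43 FPKM to 124 ± 5.53 (adjusted p = 0.0406). Gzmk, at 2.85 ± 0.062 FPKM in WT and 12.5 ± 3.15 in dKO, and Cd160, at 5.24 ± 0.374 and 2.13 ± 0.151 FPKM, did not pass (adjusted p = 0.0689 and 0.0754). Of 12 tested Th1 genes, 1 (Ccl5) rose and 0 fell, and 8 were higher adjusted over the list alone. The Th1 regulator gene Tbx21 had 10.9 ± 0.908 FPKM in WT and 20.7 ± 2.14 in dKO (adjusted p = 0.0891). Camera at the preset correlation ranked the cytotoxic list higher (adjusted p = 1.9e-05, and adjusted p = 0.375 with an estimated correlation). The Th1 list ranked higher too (adjusted p = 2.4e-05, and adjusted p = 0.375 with an estimated correlation). NK cell markers had 11 of 12 members lower in dKO and a median log2 difference of -0.51 (-0.30 without WT_1), with 0 called by limma, and 1 higher and 5 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone. Of the CD8 T cell markers, Cd8b1 had 7.75 ± 0.28 FPKM in WT and 8.85 ± 0.164 in dKO (adjusted p = 0.343), and Cd8a did not reach the filter. Without dKO_0 or without dKO_1, where 2 rows were called each, 0 of these limma calls were kept.

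Among genes that define Treg cells, the lineage factor gene Foxp3 and Il2ra, Ctla4 and Ikzf2 did not pass the test. Foxp3 had 117 ± 5.67 FPKM in WT and 138 ± 8.02 in dKO (log2 difference 0.24, limma adjusted p = 0.244). Il2ra, the gene of the IL-2 receptor chain CD25, had 99.7 ± 16.8 and 126 ± 1.0 FPKM (log2 difference 0.34, adjusted p = 0.301). The inhibitory receptor gene Ctla4 had 118 ± 6.14 and 132 ± 2.49 FPKM (log2 difference 0.16, adjusted p = 0.312). Ikzf2, the Helios gene, had 91.4 ± 3.62 and 86.8 ± 1.37 FPKM (log2 difference -0.07, adjusted p = 0.575; SD, n = 2 for each mean). Annotated genes overlap Foxp3 (Ccdc22, Flicr and Gm36995) and Ikzf2 (Gm29114). In the Treg identity list of 19 tested genes, 1 rose (Itgae) and 1 fell. Adjusted over the list alone, 2 were higher and 5 lower. The gene that fell was Ecm1, of an extracellular matrix protein, from 47.3 ± 0.0905 to 26.8 ± 0.0395 FPKM (adjusted p = 0.0286). Gpr83 had 23.8 ± 3.85 and 6.98 ± 0.872 FPKM (adjusted p = 0.0566). Lrrc32, whose protein holds latent TGF-beta on the Treg surface, had 60.1 ± 3.86 and 38.1 ± 2.79 FPKM (adjusted p = 0.102). The list's median difference was 0.12 (0.04 without WT_1 and 0.06 without dKO_0) and its mean -0.04, and camera, pointing lower and without WT_0 higher, gave no call (adjusted p = 0.593). Itgae and Ecm1 were not called without dKO_0 or without dKO_1, where 2 rows were called each.

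Genes of suppression and of effector Treg cells leaned higher. Of 18 suppressive molecules, 3 rose (Gzmb, Prf1 and Fgl2) and 0 fell, and adjusted over the list alone 4 were higher and 1 lower. The median log2 difference of the suppressive list was 0.20, and 0.09 without WT_1. Gzmb and Prf1 are also in the cytotoxic list, and so are Gzmb and Itgae of the effector Treg list. These lists share called genes and are not separate evidence. Fgl2, a secreted fibrinogen-like protein, rose from 16.5 ± 3.16 FPKM to 67.4 ± 6.39 (limma adjusted p = 0.0406). Of 29 effector Treg genes, 3 rose (Gzmb, Itgae and Id2), 0 fell and 26 did not pass. Adjusted over the list alone, 12 were higher and 1 lower. Id2, an inhibitor of E protein transcription factors, rose from 52.6 ± 1.46 FPKM to 101 ± 3.41 (log2 difference 0.93, adjusted p = 0.0272). The chemokine receptor gene Ccr2 had 8.92 ± 1.31 and 24.8 ± 1.27 FPKM (adjusted p = 0.0504), and the galectin-1 gene Lgals1 had 239 ± 11 and 456 ± 32.4 FPKM (adjusted p = 0.0566). The authors' deposited lists held 10 effector Treg genes as higher and 0 as lower. The median log2 difference of the effector list was 0.33, and 0.51 without WT_0 and 0.17 without WT_1. Camera ranked the effector list higher (adjusted p = 2.3e-05, and adjusted p = 0.393 with an estimated correlation) and the suppressive list too (adjusted p = 0.0211, and adjusted p = 0.44 with an estimated correlation). Without WT_1 the suppressive list had an adjusted p = 0.131, in a range of 0.00147 to 0.44 over its alternatives. Without dKO_0 or without dKO_1, where 2 rows were called each, 0 of these limma calls were kept.

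Genes of resting and naive T cells leaned lower. Of 26 tested members, 2 fell, 0 rose and 24 did not pass. Adjusted over the list alone, 12 were lower and 1 higher. Actn1, the gene of the actin crosslinker alpha-actinin, fell from 67.6 ± 0.788 FPKM to 30.7 ± 0.958 (SD, n = 2 each; log2 difference -1.11, limma adjusted p = 0.0135). Il6st, which encodes the shared receptor chain gp130, fell from 56.7 ± 2.64 FPKM to 29.1 ± 1.02 (log2 difference -0.94, adjusted p = 0.0318). The IL-6 receptor gene Il6ra had 63 ± 4.15 and 37.4 ± 1.8 FPKM (adjusted p = 0.0724), and the transcription factor gene Bach2 had 14.7 ± 0.459 and 9.38 ± 0.253 FPKM (adjusted p = 0.0884). Genes on the opposite strand overlap Actn1, Il6ra and Bach2. Camera ranked the list lower (adjusted p = 1.5e-05, and adjusted p = 0.375 with an estimated correlation). Monocyte and macrophage markers were lower in 18 of 18 members, and in 17 with any 1 library left out, with a median of -0.38, 0 called by limma, 10 lower at an unadjusted p under 0.05 and 8 lower adjusted over the list alone. Plasma cell markers were lower in 5 of 5, and in 3 of 4 without WT_0, with 0 called and 4 lower at an unadjusted p under 0.05, and 0 higher and 4 lower adjusted over the list alone. Actn1 and Il6st were not called without dKO_0 or without dKO_1, where 2 rows were called each.

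Wnt/beta-catenin targets, a list that includes Tcf7 and Lef1, were lower in 9 of 10 tested members, and in 6 without WT_1. By limma 0 were called, 4 were lower at an unadjusted p under 0.05, and 3 were lower adjusted over the list alone. Tcf7 and Lef1, the targeted genes, were in both counts, and the list was not tested without them. Rnf43, a Wnt feedback inhibitor gene, had 17.6 ± 3.13 FPKM in WT and 11.6 ± 0.91 in dKO (limma adjusted p = 0.197). Camera ranked the list lower (adjusted p = 0.00333, and adjusted p = 0.44 with an estimated correlation), with an adjusted p = 0.0953 without WT_1 (range over its alternatives 1.5e-04 to 0.44). Follicular genes were lower in 12 of 16 (median log2 difference -0.30, and -0.06 without WT_0), with 0 called by limma, 5 lower and 1 higher at an unadjusted p under 0.05, and 4 lower adjusted over the list alone. Camera ranked them lower (adjusted p = 0.0133, and adjusted p = 0.536 with an estimated correlation), with an adjusted p = 0.562 without WT_0 (range over its alternatives 1.0e-06 to 0.562). Il1r2, an IL-1 decoy receptor gene, had 23.4 FPKM in WT_0, 8.23 in WT_1, 7.79 in dKO_0 and 7.3 in dKO_1.

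Cell cycle genes were higher in dKO in all 44 of 44 tested members, also after quantile normalization or median centring, with a median log2 difference of 0.72. All 44 were lowest in WT_1, and without WT_1 all 44 were still higher in dKO, with a median of 0.55, against 0.84 without WT_0. By limma over all genes 0 were called, 40 were higher at an unadjusted p under 0.05, and 38 were higher adjusted over the list alone. The authors' deposited lists held 27 as higher and 0 as lower. Birc5, the survivin gene, had 19.9 ± 5.0 FPKM in WT and 38.8 ± 2.11 in dKO (SD, n = 2 each; limma adjusted p = 0.152). Top2a, a DNA topoisomerase gene of dividing cells, had 22 ± 4.97 and 42 ± 5.26 FPKM (adjusted p = 0.158). Rrm2, of nucleotide synthesis, had 21.9 ± 4.32 and 41.9 ± 1.89 FPKM (adjusted p = 0.124). Camera gave an adjusted p = 7.3e-20, and an adjusted p = 0.44 with an estimated correlation. Replication-dependent histones were higher in 6 of 8, with 0 called and, at an unadjusted p under 0.05, 5 higher and 1 lower, with 4 higher and 1 lower adjusted over the list alone. B cell markers were higher in 14 of 14, with 0 called by limma and 0 at an unadjusted p under 0.05 or adjusted over the list alone, and 13 of the 14 were lowest in WT_1. Without WT_1, 9 of 14 were higher, with a median log2 difference of 0.09, against 0.67 with all libraries, 1.39 without WT_0 and 1.02 without dKO_0.

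**Figure D2:**
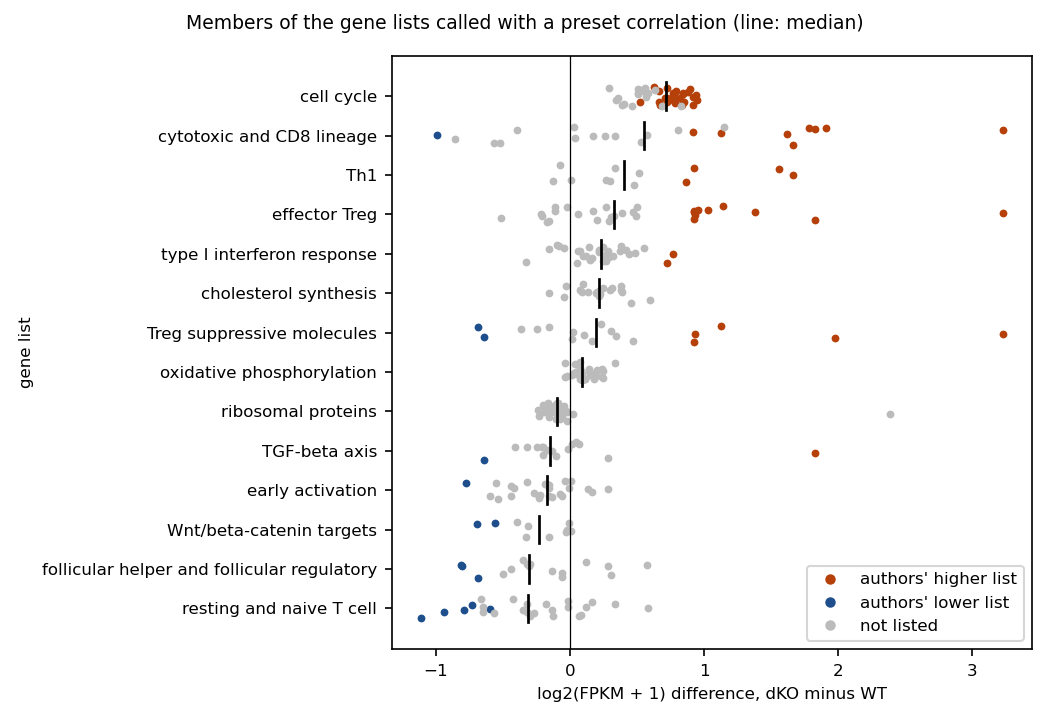
Log2(FPKM + 1) difference, dKO minus WT, of each tested member of the 14 lists called by camera at the preset correlation, coloured by the authors' lists, with a black line at each median. All cell cycle members lie above 0, with a median of 0.72, and resting and naive T cell members have a median of -0.31.

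Type I interferon response genes were higher in 25 of 30 members, with a median log2 difference of 0.23. Of the 30, 17 were lowest in WT_1 and 19 highest in dKO_1, and without dKO_1 21 of 29 were higher, with a median of 0.15. By limma 0 were called, 11 were higher at an unadjusted p under 0.05, and 6 were higher adjusted over the list alone. Gbp2, an interferon-induced GTPase gene, had 51.9 ± 3.35 FPKM in WT and 86.5 ± 5.13 in dKO (limma adjusted p = 0.0768). Camera ranked the list higher (adjusted p = 7.5e-05, and adjusted p = 0.44 with an estimated correlation). Of 29 chemokine receptor and homing genes, 1 rose (Itgae) and 0 fell, and adjusted over the list alone 10 were higher and 3 lower. Cxcr3 had 76.8 ± 10.9 and 147 ± 20.04 FPKM (adjusted p = 0.122). Camera gave no call for this list (adjusted p = 0.0555, and adjusted p = 0.44 with an estimated correlation), and an adjusted p = 0.0204 without WT_1 and 0.0144 without dKO_1, in a range of 0.00503 to 0.44 over its 11 alternatives, 5 of which called it. Of 41 T cell transcription factor genes, which include Tcf7 and Lef1, 1 rose (Id2) and 0 fell. Adjusted over the list alone, 9 were higher and 8 lower. The Blimp1 gene Prdm1 had 6.45 ± 2.62 and 12.7 ± 0.195 FPKM (adjusted p = 0.222). The median of this list was -0.07 (-0.03 without WT_0, -0.01 without WT_1, -0.02 without dKO_0 and -0.04 without dKO_1), its mean 0.04, and camera, pointing lower, gave no call (adjusted p = 0.593). Itgae and Id2 were not called without dKO_0 or without dKO_1, where 2 rows were called each.

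Camera gave no call for IL-2 and STAT5 axis genes, inhibitory receptors, Th2, Th17, survival and glycolysis genes, and limma called 0 members of each. Of 16 IL-2 and STAT5 axis genes, 5 were higher and 1 lower at an unadjusted p under 0.05, and 2 were higher adjusted over the list alone (camera adjusted p = 0.198). The kinase gene Pim1 had 141 ± 14.2 FPKM in WT and 239.6 ± 13.1 in dKO (limma adjusted p = 0.0942). Of 13 inhibitory receptors, 1 was higher and 4 were lower at an unadjusted p under 0.05, and 3 were lower adjusted over the list alone (camera adjusted p = 0.593, pointing lower with a mean of -0.03 and a median of 0.14, which was 0.06 without WT_1, 0.06 without dKO_0 and 0.09 without dKO_1). The PD-1 gene Pdcd1 had 72.4 ± 20.8 and 43.8 ± 4.08 FPKM (adjusted p = 0.251). At an unadjusted p under 0.05, 1 of 9 Th2 genes was higher and 1 lower, 3 of 8 Th17 genes were higher and 0 lower, 2 of 22 survival genes were higher and 1 lower, and 1 of 19 glycolysis genes was higher and 3 lower. Adjusted over the list alone, 3 Th17 genes and 1 glycolysis gene were higher, and 0 Th2 or survival genes passed. The camera adjusted p was 0.593 for Th2, 0.185 for Th17, 0.593 for survival and 0.627 for glycolysis genes.

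Heat shock genes were lower in 15 of 18 members, with a median log2 difference of -0.37. By limma 0 were called, 9 were lower and 1 higher at an unadjusted p under 0.05, and 6 were lower and 1 higher adjusted over the list alone. The chaperone gene Hsph1 had 127 ± 18.7 FPKM in WT and 61.3 ± 8.65 in dKO (limma adjusted p = 0.118), and 12 of the 18 were highest in WT_1, among them Hspa1b and Dnajb1, at 38 and 173 FPKM. General T cell genes were higher in 9 of 11 members, in 6 after quantile normalization and in 7 without WT_1, with 0 called and 3 higher at an unadjusted p under 0.05, and 1 higher and 0 lower adjusted over the list alone. Among conventional CD4 T cell genes, which include Tcf7, 0 of 10 were called by limma. At an unadjusted p under 0.05, 2 were higher and 4 lower, and adjusted over the list alone 2 were higher and 3 lower. Among dendritic cell markers 0 of 10 were called, with 2 higher and 0 lower at an unadjusted p under 0.05, and 1 higher and 0 lower adjusted over the list alone. Among erythroid and platelet markers 0 of 11 were called, with 0 at an unadjusted p under 0.05 or adjusted over the list alone. Of these 11, 9 were highest in WT_0, and the authors' deposited lists held 2 as lower and 0 as higher. Their median log2 difference was -0.16, against -1.13 without WT_1 and 0.48, over 8 members, without WT_0.

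The authors' deposited lists held 185 genes as higher and 147 as lower in dKO. Of these, 321 passed the filter, all 321 with the same sign in the limma fit, and 263 had an unadjusted p under 0.05. The WT and dKO libraries did not overlap for 181 of the higher and 102 of the lower genes. The authors selected these genes on the same libraries, so no chance rate is set against those counts. Over all 11595 tested rows the groups did not overlap, in either order, in 51.2%, where chance gives 33.3% for a single row. Rows vary together within a library, so the share over all rows can differ from 33.3% without an effect of genotype. Without WT_0, 178 of the higher and 87 of the lower genes kept a fold of at least 1.5 in mean FPKM, and 163 and 131 without WT_1, 179 and 140 without dKO_0, and 176 and 138 without dKO_1.

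Intestinal epithelial genes were among the lower list. A list of 44 such genes, written after the data were seen, had 21 members in the authors' lower list and 0 in the higher list, and all 44 were highest in WT_0. The members were settled with their values in view, so these counts are no test. Of 44 intestinal genes named before their values were seen, 40 were kept and 4 were not. Of those not kept, Chga, Dclk1 and Olfm4 were under an FPKM of 1 in every library, and Lyz1 was highest in WT_1, at 22.3 FPKM against 19.2 in WT_0. After that, 4 more, among them Cdhr2, Cdhr5 and Myo1a, were added from the authors' lower list after their values were seen, and 10 genes of smooth muscle, stroma, liver and pancreas were looked at and not kept. The bile acid-binding protein gene Fabp6 had 187 FPKM in WT_0, 46.2 in WT_1, 75.1 in dKO_0 and 39.8 in dKO_1. By limma 0 of 37 tested members were called, with 0 at an unadjusted p under 0.05. Neutrophil markers were lower in 9 of 11, but in 5 without WT_0, with 6 in the authors' lower list and 1 higher and 0 lower adjusted over the list alone. S100a8, an abundant neutrophil gene, had 153 FPKM in WT_0, 35.3 in WT_1, 30.9 in dKO_0 and 41.7 in dKO_1. The called neutrophil marker, Mmp9, was higher in dKO and was not called without dKO_0 or without dKO_1, where 2 rows were called each.

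**Figure D3:**
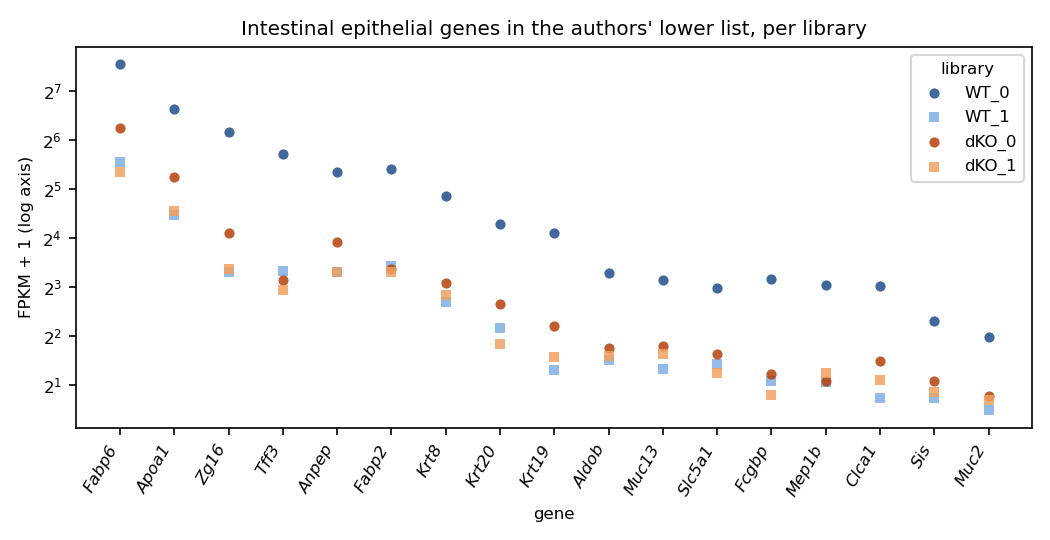
FPKM + 1 on a log axis for the 17 intestinal epithelial genes in the authors' lower list that were named before their values were seen, with 1 point per library. WT_0 is the highest library for all 17, as for Fabp6 with 187 FPKM in WT_0 and 46.2 in WT_1.

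Small RNA rows made up 15 of the calls, 5 higher and 10 lower, and 13 of them were listed at 0 in both libraries of a group. Scarna17, a guide RNA of Cajal bodies, was listed at 0 in both WT libraries and at 702 and 655 FPKM in dKO_0 and dKO_1. The small nucleolar RNA Snord38a had 2705 FPKM in WT_0 and 559.8 in WT_1 and was listed at 0 in both dKO libraries. The test called 6.7% of 224 small RNA rows and 0.22% of the others. The authors' deposited lists held 0 small RNA rows.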

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

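Leaving out small RNA rows, the crossed pairing and the list tests after rescaling were chosen after seeing the data. The 40 calls (21 higher, 19 lower) moved to 16 (10 and 6) without a filter, 185 (122 and 63) with robust moderation, 186 (128 and 58) without small RNA rows, 12 (8 and 4) at an adjusted p under 0.01 and 131 (89 and 42) at 0.1. With each library left out they ranged from 2 to 217, with 0 to 134 higher and 2 to 86 lower. A group then held 1 library, assumed to vary like the other group. The cause of these moves was not tested. The 25 called genes that are not small RNAs kept their sign under all alternatives run, except Klk1b22, which left the filter without dKO_0 or dKO_1. Fewer stayed called: 6 without a filter, 15 without the trend and 7 with the crossed pairing. A filter at an FPKM of 5 or quantile normalization kept 22. All 25 stayed called with the other pseudocounts, median centring, robust moderation or small RNA rows left out.

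As a replicate block, the column suffixes gave 7 calls, 5 higher and 2 lower, all small RNA rows, and the other 25 genes kept an unadjusted p under 0.05. The suffixes are not tied to the titled replicate numbers, nothing says that they pair mice, and deviations of equal suffixes correlated at -0.11 across genes. The crossed pairing gave 22 calls, 14 higher and 8 lower.

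Lef1, with a log2 difference of -0.70, passed with robust moderation (adjusted p = 0.0317) and without small RNA rows (adjusted p = 0.0353), in a range of 0.0317 to 0.521. Tcf7 did not pass, at 0.0697 to 0.636. The 14 list calls were 0 with an estimated correlation, where camera also had only 2 degrees of freedom, and 11 to 15 under the other alternatives. The authors' 332 listed genes were 214 at a q under 0.01 and 158 at a fold of at least 2. Without a call either way, camera's direction turned for Treg identity without WT_0 (adjusted p = 0.78, range 0.526 to 0.807, with 0.58 to 0.78 when each library was left out) and for glycolysis without WT_1 (0.363, with 0.109 to 0.835 when each library was left out) and after quantile normalization (0.89, range 0.109 to 0.89). Count models were not run, since the values are not counts. The depth limits what can be said of low genes and short rows.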

Other observations

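All tests of explanations in this part were chosen after the results were seen, while the gene lists were fixed earlier except the intestinal list.

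Genes of cholesterol synthesis leaned higher in dKO, in 17 of 20 members. By limma 0 were called, 9 were higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Camera ranked the list higher (adjusted p = 1.3e-04, and adjusted p = 0.44 with an estimated correlation). Oxidative phosphorylation genes were higher in 28 of 31, by a median of 0.09 (0.19 without WT_0 and 0.03 without WT_1), with 0 called by limma, 4 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone. Their camera adjusted p was 0.00173, with an adjusted p = 0.64 with an estimated correlation and 0.441 without WT_1 (range over its alternatives 4.6e-06 to 0.64). Early activation genes were lower in 23 of 27, with 0 called by limma, 10 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 9.7e-05, and adjusted p = 0.393 with an estimated correlation). The phosphatase gene Dusp1 had 59 ± 17.7 FPKM in WT and 33.3 ± 0.563 in dKO (SD, n = 2 each; limma adjusted p = 0.218), and was highest in WT_1, at 71.5 FPKM against 46.5 in WT_0. Of the 27 early activation genes, 16 were highest in WT_1. Heat shock genes were lower in dKO too, in 15 of 18 with a median of -0.37, and 12 of the 18 were highest in WT_1. Handling of the cells and the genotype both stay open here.

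In the TGF-beta axis list, 1 of 16 genes rose (Itgae), 0 fell, and adjusted over the list alone 1 was higher and 3 were lower. Camera ranked the list lower (adjusted p = 0.0161, and adjusted p = 0.44 with an estimated correlation), with an adjusted p = 0.189 without WT_1 (range over its alternatives 0.0101 to 0.44). Itgae was not called without dKO_0 or without dKO_1, where 2 rows were called each. Ribosomal protein genes were lower in 32 of 34, and in 22 after quantile normalization, with 0 called by limma and 0 at an unadjusted p under 0.05 or adjusted over the list alone (camera adjusted p = 0.00255, and adjusted p = 0.64 with an estimated correlation). The camera adjusted p was 0.222 without WT_0, 0.287 without dKO_1 and 0.62 after quantile normalization (range over its alternatives 6.3e-07 to 0.64).

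The intestinal genes in the authors' lower list may come from intestinal RNA in WT_0, a library of sorted spleen cells, and this stays open. The 17 tested members that the authors did not list were higher in WT_0 than in WT_1 by a median of 1.79 on the log2 scale, but the list was settled with these values in view, so this describes the members and tests nothing. The genotype is argued against: WT_1 was at least 1.5 times the dKO mean in 0% of the 21 listed genes, 17 of which were named before their values were seen. A complete CD4+ GFP+ sort would remove epithelial cells. RNA of markers of other cells was still found in both groups, as for the macrophage marker C1qa (means of 103 FPKM in WT and 77.9 in dKO) and the plasma cell marker Jchain (247 and 127). The sort therefore does not decide the question. Of the 44 genes, 0 are in a fixed list.

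The higher cytotoxic genes could come from NK or CD8 T cells in the dKO libraries. A gain of NK cells is argued against, by markers whose values were already in view. The 8 tested NK markers outside the cytotoxic list were all lower in dKO, with a median log2 difference of -0.53 (range -0.63 to -0.28). Of all 12 tested NK markers, 0 passed adjusted over the list alone and 10 were highest in WT_1. Without WT_1, 11 of the 12 were still lower, with a median of -0.30. For CD8 T cells, Cd8a and Cd8b1 together gained 1.64 FPKM, 0.332% of the 493 FPKM gained by Gzmb, Nkg7, Ccl5 and Prf1. No level of these genes in CD8 T cells was used for comparison, so that source and a change within Treg cells cannot be told apart here. A complete CD4+ GFP+ sort would remove CD8 T cells, but how complete the sort was is not known. The genotype stays open as well.

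The small RNA calls may reflect short, sparsely sampled rows, with a median length of 89 nucleotides against 2558 for other tested rows. Splitting the 4 libraries in the 2 other ways, each with 1 WT and 1 dKO library per side, called 10 and 11 small RNA rows, against 15 in the real split. These were all the rows that the other splits called. With small RNA rows left out, they called 0 rows each, against 186 in the real split. Any difference between WT and dKO adds spread within the sides of a mixed split, so these counts do not measure a rate of false calls. Between dKO_0 and dKO_1, some FPKM stood as equal read numbers would at the estimated depths, 1.01 and 1.09 relative to WT_1. Such rows were Scarna17 (702 and 655), Mir1949 (286 and 267) and Mir6418 (35.7 and 33.3), but not Mir7653 (398 and 266). Equal read numbers leave little spread between libraries, so the small limma p-values of such rows are weak evidence. An effect of genotype on part of the small RNA rows stays open.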
